A study of Mus musculus with 21 samples.

How the data were processed

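RNA from the mouse melanoma line B16-F10 was measured on 21 Affymetrix Murine Genome U74Av2 arrays. Per the labels, cells were kept for 24 h at 1% oxygen or with 100 µM or 200 µM cobalt chloride (CoCl2), and controls were kept at 21% oxygen for a time that the labels do not give. The deposited values are log2 RMA values, 1 per probe set and array, and the submitters' processing notes name GCOS 1.2 and RMA. The version of RMA, the probe definition and whether all 21 arrays went through RMA in 1 run are not given in the sources used here. The values ran from 1.37 to 13.3, and array medians lay between 5.44 and 5.53, so the arrays had been placed on 1 scale by the authors. The deposited values were used without further scaling.

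The labels form 9 groups. The chamber set had 2 controls and 3 hypoxia arrays, experiments 1 and 2 (flow-regulated incubator) each had 2 controls and 3 hypoxia arrays, and experiment 3 had 2 controls and 2 arrays at each CoCl2 dose. The controls of the chamber set were assigned to it because their titles, like those of the chamber arrays, carry no experiment number. The treatment protocol names a chamber and an incubator, and each set used 1 device, so device and set cannot be separated from the chamber arrays alone. The labels call arrays of a group biological replicates and do not say whether each came from a separately grown culture, so p-values measure the spread between these arrays and no more. Samples were not treated as paired by replicate number. Residuals of arrays with the same number correlated between -0.370 and 0.235, with no common sign. In a group of 2 arrays the residuals mirror each other, so these values are few and do not exclude pairing.

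Of 12488 probe sets, 66 were Affymetrix controls and 11251 had a gene annotation. Probe sets assigned to several genes (396) were left out, and 10833 with 1 gene symbol were kept, of which 10817 were matched to current symbols by Entrez identifier and 16 kept an older symbol. Probe sets without a gene name in the annotation used here (1193) were not tested by name. Where a gene had several probe sets (2073 genes), the one with the highest mean represented the gene, which left 8251 genes. The rule fixed beforehand set aside sets ending in _x_at, of which there were 0, so cross-hybridising sets were not removed. Sets ending in _f_at, which match a sequence family, represented 395 genes, among them H2-K1, H2-D1, Pkp2 and Atf3. No detection calls were used here. The 3′ and 5′ control probe sets of Actb and Gapdh measured RNA quality as their difference per array.

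A linear model with 1 mean per group was fitted to all 21 arrays with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom (20.9 after empirical Bayes moderation). The hypoxia effect is the mean, with equal weight, of the differences between hypoxia and control within the chamber set, experiment 1 and experiment 2. CoCl2 was compared with the controls of experiment 3 at each dose and as the mean of both doses. Differences of differences compared the chamber with the incubator, experiment 1 with experiment 2, and CoCl2 with hypoxia. All tests were two-sided, p-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Errors are standard errors of the model.

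Each of 25 gene lists was tested with camera (limma, preset correlation 0.01), adjusted over the 25 lists, then again with a correlation estimated from the residuals, and with fry. Camera compares a list with the other genes. Fry's p-value tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Genes within lists were also counted with p-values adjusted over the list alone. The comparisons, the lists, the rule for naming genes, the choice of probe sets and most alternatives were fixed before the data were examined. Selenbp1 and Lgals3 were placed in lists from memory of earlier hypoxia work on this cell line, so their direction there is not independent evidence. With both removed, 8 lists were still called for hypoxia.

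Genes were named by rule. For hypoxia these were the 12 highest and 12 lowest changes among genes called for the mean with 1 sign in the 3 sets. For CoCl2 they were the 10 highest and 10 lowest among genes called at 200 µM with the same sign at 100 µM. Differences of differences, single hypoxia sets and the dose comparison gave up to 6 in each direction, and each list gave up to 6 members with the largest changes. A short fixed set was always looked at, among them Vegfa, Hif1a, Epas1, Tyr, Mt1, Mt2, Cdkn1a, Mki67 and Tfrc. Other probe sets of each named gene were examined, and disagreements are given with the gene.

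Alternatives were median centring or quantile normalisation of the arrays, leaving out genes with a mean under the 40th percentile, all probe sets or their mean, a variance trend with robust moderation, array weights, replicate number as a block, only arrays of the compared sets, an adjusted p under 0.01, a change of at least 1 log2 unit, an additive model, a model that ignored the sets, leaving out each set from the mean, and leaving out each array. Where a group was left with 1 array, that array was assumed to vary like those of the other groups. The Actb 3′ minus 5′ value as a covariate, crossed replicate numbers, 1 control array for each CoCl2 dose, leaving out sets ending in _f_at and the lists without Selenbp1 and Lgals3 were added after the data were seen. Neither scaling moved the median change of all genes by 0.1 log2 units in any comparison.

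The procedure was tested on simulated data with the same groups. For hypoxia, 35 of 35 simulated changes of 0.5 log2 units were recovered, with 3 false calls among 128. At 200 µM CoCl2, 4 of 15 changes of 0.5 and 14 of 15 changes of 1 log2 unit were recovered, and for the chamber minus incubator difference 1 of 10 and 10 of 10. The 1 shifted list was called and none of the 24 others was. Noise was simulated as independent between genes and with 1 spread per gene for all arrays. Real CoCl2 pairs varied more (SD of the difference 0.395 at 100 µM and 0.330 at 200 µM, elsewhere at most 0.250). Recovery with CoCl2 and the list result may therefore be too favourable for these arrays. For arrays, the number per group limits the precision. The median standard error of a log2 change was 0.07 for hypoxia, 0.13 within a hypoxia set and 0.14 for each CoCl2 dose. Random regroupings used seed 1.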

Results

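B16-F10 is a melanotic melanoma line from C57BL/6J mice. Its transcriptome was measured on 21 arrays at 21% oxygen (control), after 24 h at 1% oxygen (hypoxia) or after 24 h with CoCl2, a salt used by the submitters to mimic hypoxia. Hypoxia was produced in a sealed chamber (3 arrays, 2 controls) or in a flow-regulated incubator in experiments 1 and 2 (3 arrays and 2 controls each). Experiment 3 held 2 control arrays, 2 arrays at 100 µM CoCl2 and 2 at 200 µM CoCl2. Precision is limited by these numbers of arrays. Arrays of the same group correlated between 0.992 and 0.998 across genes, except the CoCl2 pairs at 100 µM (0.981) and 200 µM (0.987); genes are not independent replicates.

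Measures of RNA quality differed between the sets for Actb and Gapdh, and not for every control gene. The Actb 3′ minus 5′ signal, which grows as RNA is degraded or incompletely copied, was 0.15 to 0.50 log2 units in the 15 arrays of the hypoxia sets. In experiment 3 it was 1.41 and 1.62 in the controls, 2.36 and 2.16 at 100 µM CoCl2, and 1.47 and 0.50 at 200 µM. The Gapdh values were 0.07 to 0.52 in the hypoxia sets and 0.12 to 2.21 in experiment 3, where the highest was in control array 1. Values of the transferrin receptor control overlapped, from 1.56 to 2.60 in the hypoxia sets and 1.66 to 2.41 in experiment 3. Those of the pyruvate carboxylase control were 0.43 to 0.96 in the hypoxia sets and 0.60 to 1.21 in experiment 3.

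**Figure D1:**
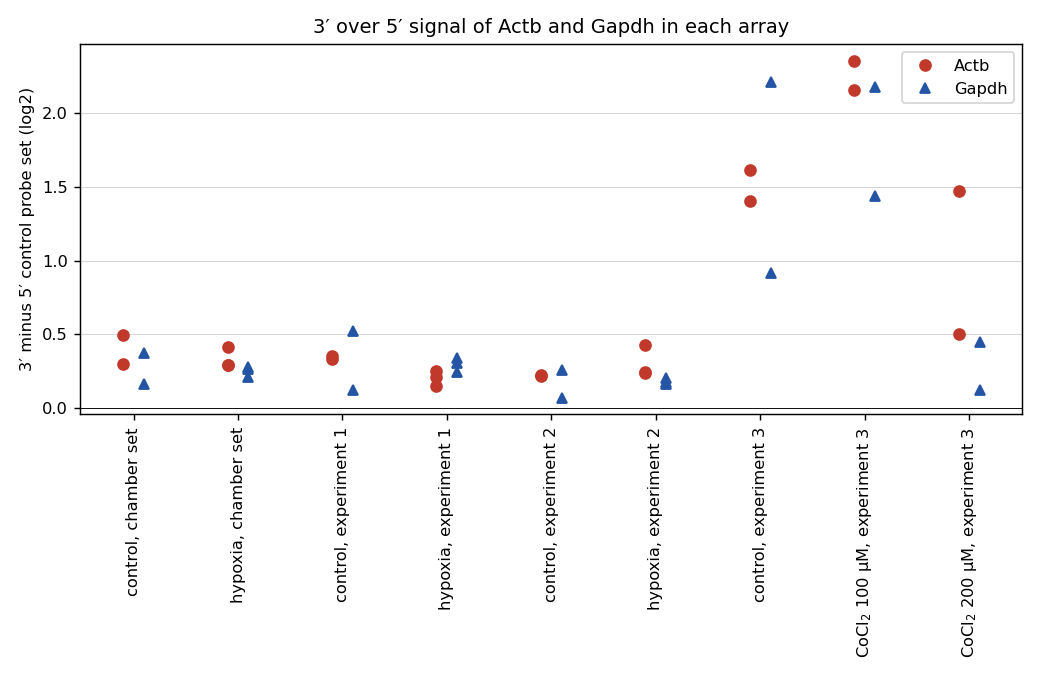
Difference between the 3′ and 5′ control probe sets (log2 units, vertical axis) of Actb (circles) and Gapdh (triangles) in each array, by group (horizontal axis). Actb values lie between 0.15 and 0.50 in the hypoxia sets and reach 2.36 at 100 µM CoCl2.

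The first question was which genes low oxygen changed across the 3 hypoxia sets (9 hypoxia and 6 control arrays). The highest rise was that of Lgals3, which encodes the lectin galectin-3, by 4.10 ± 0.12 log2 units (SE; 17.2-fold; adjusted p = 7.0e-17). Its control means were 3.76 in the chamber set and 3.90 in experiment 1, lower than in experiment 2, and a level above background was not tested in these arrays, so the fold is uncertain. Nppb, the precursor of B-type natriuretic peptide, rose by 3.74 ± 0.09, the selenium-binding protein gene Selenbp1 by 3.64 ± 0.09, the atypical cyclin gene Ccng2 by 3.18, and the matricellular growth factor gene Ccn2 by 2.98. Ahr (aryl hydrocarbon receptor, 2.85), Vcl (vinculin of cell adhesions, 2.82), Pkp2 (plakophilin of desmosomes, 2.81), Bnip3 (mitophagy receptor, 2.76), Pfkp (phosphofructokinase, 2.75), Adm (the vasodilator adrenomedullin, 2.61) and Vegfa (vascular endothelial growth factor, 2.52) also rose. The deepest falls were those of Rrm2, a subunit of ribonucleotide reductase (-1.64 ± 0.11; adjusted p = 1.9e-10), and Cdc6, which loads the replicative helicase (-1.62 ± 0.08). Cdca7 (-1.45), Limch1 (-1.42), the peptidylprolyl isomerase gene Ppid (-1.38), the glutamine transporter gene Slc1a5 (-1.35), the splicing factor gene Srsf1 (-1.31), the flap endonuclease gene Fen1 (-1.29), Cyb5r1 (-1.28), the pre-rRNA processing gene Bop1 (-1.27), Mid1ip1 (-1.27) and Rbm38 (-1.27) fell as well. In total 2642 of 8251 genes changed, 1036 higher and 1606 lower, and 2428 of them had 1 sign in the 3 sets. A change of at least 1 log2 unit was seen for 111 genes higher and 49 lower. Other probe sets did not pass the test for Srsf1 (-0.02 and -0.33), Cyb5r1 (-0.06) and Bop1 (0.06).

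**Figure D2:**
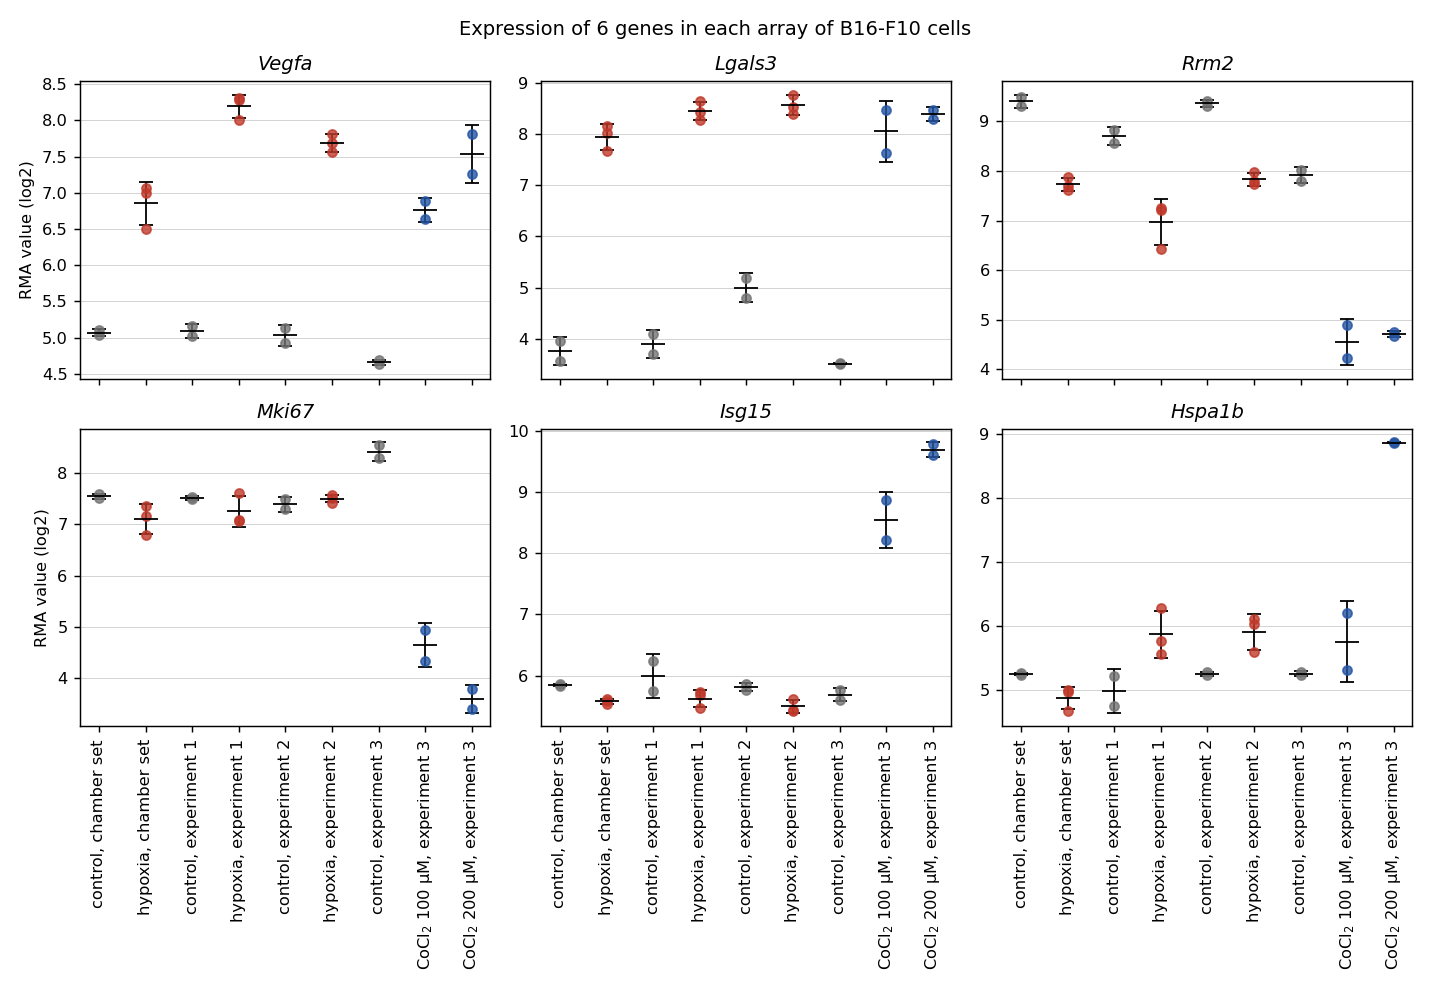
RMA values (log2, vertical axis) of 6 genes in each array (points), with the mean and SD of each group of 2 or 3 arrays (horizontal axis). Vegfa and Lgals3 are higher in hypoxia and with CoCl2 than in the controls of each set, while Isg15 rises from 5.68 to 9.69 at 200 µM CoCl2. In hypoxia the Isg15 means lie between 5.50 and 5.62, below those of the controls of the same sets (5.82 to 5.99).

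Glucose metabolism and targets of the hypoxia-inducible factor (HIF) rose. Of 18 measured genes of glycolysis and glucose uptake 15 rose, none fell and 3 did not pass (median 0.64, camera adjusted p = 2.2e-16). Examples are the glucose transporter Slc2a1 (2.38), the hexokinase Hk2 (2.07), the enolase Eno2 (1.88), and the smaller changes of Pgk1 (0.61) and Ldha (0.39). Of 21 HIF targets outside glycolysis 19 rose (median 1.64, adjusted p = 2.5e-26), among them the transcriptional repressor Bhlhe40 (2.33), the oxidoreductase Ero1a (2.17) and the HIF prolyl hydroxylase Egln1 (2.11); this list holds Selenbp1. Of 12 glycogen genes 6 rose and 1 fell (median 0.21, adjusted p = 0.00024), with the branching enzyme Gbe1 (2.39), the glycogen synthase Gys1 (2.34) and the phosphoglucomutase Pgm1 (1.55) highest. Extracellular matrix and invasion genes included 19 of 42 that rose and none that fell (median 0.15, adjusted p = 2.9e-06), such as the integrin Itga4 (1.51), the adhesion molecule Mcam (1.22) and the fibronectin gene Fn1 (1.09); this list holds Lgals3. Counts adjusted over the list alone were the same in these 4 lists, and the calls held with an estimated correlation (adjusted p = 0.0062, 0.00086, 0.0062 and 0.00086). A further probe set did not pass for Hk2 (0.06) and Itga4 (0.12).

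Genes of proliferation fell. Of 40 DNA replication genes 35 fell, 36 adjusted over the list alone, and none rose over all genes (median -0.70, camera adjusted p = 2.6e-21; with Rrm2, Cdc6, Fen1, Uhrf1 at -1.17 and the helicase subunit Mcm2 at -0.99). Of 42 ribosome biogenesis genes 29 fell and 1 rose, 30 and 2 adjusted over the list alone (median -0.44, adjusted p = 1.2e-11), with the nucleolar protein gene Nop56 at -1.16 (a further probe set at -0.25 did not pass). Both calls held with an estimated correlation (adjusted p = 0.0043 and 0.012), but in experiment 1 alone ribosome biogenesis was not called (11 fell, 4 rose, median -0.11, adjusted p = 0.23). Of 38 mitosis genes 22 fell and 2 rose, 23 and 2 adjusted over the list alone (median -0.24, adjusted p = 1.9e-05), with Cenpa at -0.69 and Kif23 at -0.68, while the proliferation marker Mki67 (-0.20, adjusted p = 0.19; 0.027 with array weights) did not pass. The mitosis call was lost at adjusted p = 0.37 with an estimated correlation, and in experiment 2 alone the list was not called (5 fell, 2 rose, adjusted p = 0.25). Of 25 tricarboxylic acid cycle genes 10 fell and none rose, also adjusted over the list alone (median -0.16, adjusted p = 0.0028), among them the isocitrate dehydrogenases Idh2 (-0.61) and Idh1 (-0.51). That call was lost as well, at adjusted p = 0.45 with an estimated correlation, and in neither experiment 1 nor experiment 2 alone was the list called (adjusted p = 0.23 in each). Camera called 8 of the 25 lists, 6 held with an estimated correlation, and fry, whose test does not compare a list with other genes, called 21.

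The other 17 lists were not called for hypoxia. The transcripts of the HIF subunits themselves did not pass (Hif1a 0.04, adjusted p = 0.79; Epas1 -0.08, adjusted p = 0.51), and among 14 HIF pathway components 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.13). Oxidative phosphorylation had 13 falls and 1 rise among 45 genes, 14 and 1 adjusted over the list alone (median -0.12, adjusted p = 0.13). Among 20 angiogenic factors 6 rose and 6 fell, 7 and 6 adjusted over the list alone (adjusted p = 0.25). Of 18 melanocyte and pigment genes 7 fell and 2 rose, 8 and 3 adjusted over the list alone (adjusted p = 0.25): the pigment transport genes Mlph (-0.96) and Gpr143 (-0.95) fell and the lineage regulator Mitf rose by 0.89, while the melanogenic enzymes Tyr (0.03), Tyrp1 (-0.06) and Dct (-0.08) did not pass. Interferon and antigen presentation genes went both ways, 3 up and 5 down of 33, 3 and 4 adjusted over the list alone (median -0.01, mean 0.06, camera direction up, adjusted p = 0.91), although the class I genes H2-K1 (2.05, with a further probe set at -0.01) and H2-D1 (1.55) rose. Of 22 heat shock genes 4 rose and 8 fell, 6 and 8 adjusted over the list alone (median 0.01, mean -0.13, camera direction down, adjusted p = 0.34), with Hsph1 at -1.11. Markers of other cell types moved little: no fibroblast marker of 13 passed with limma adjusted over all genes or over the list alone (camera adjusted p = 0.25), and 1 of 12 epithelial markers rose, 0 adjusted over the list alone (adjusted p = 0.33). Of 10 endothelial markers 1 fell, also adjusted over the list alone (adjusted p = 0.74), and of 13 leukocyte markers 2 rose, 1 adjusted over the list alone (adjusted p = 0.14). That leukocyte list includes Cd68 (0.84, with a further probe set at 0.09).

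**Figure D3:**
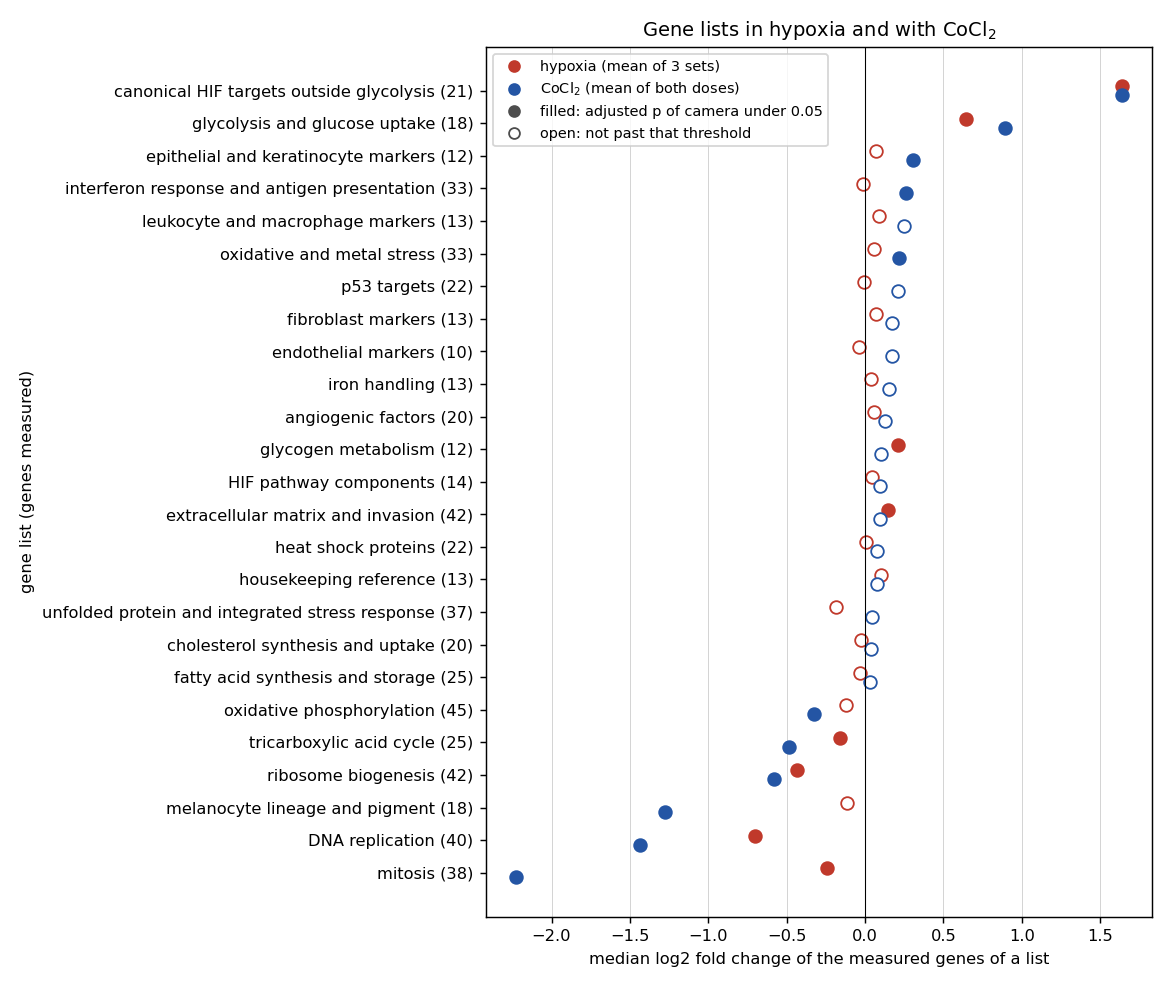
Median log2 change (horizontal axis) of the measured genes of each of 25 lists (vertical axis, number of genes in parentheses) for hypoxia (red) and the mean of both CoCl2 doses (blue); filled points passed camera at an adjusted p under 0.05. HIF targets reach 1.64 under both treatments, and the mitosis median is -0.24 in hypoxia and -2.22 with CoCl2.

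The sets were then compared with each other. Lgals3 rose by 4.18 in the chamber set, 4.56 in experiment 1 and 3.57 in experiment 2, Bnip3 by 3.13, 1.76 and 3.38, and Vegfa by 1.78, 3.11 and 2.66. The chamber set gave 1899 changed genes (657 higher, 1242 lower), experiment 1 gave 1510 (625 higher, 885 lower) and experiment 2 gave 1266 (623 higher, 643 lower). Of these, 255 genes were called higher and 384 lower in each of the 3 sets. Log2 changes correlated across genes at 0.645 between the chamber set and experiment 1, 0.746 between the chamber set and experiment 2, and 0.799 between experiments 1 and 2, with no control array in common; genes are not independent replicates. Counts fell to 1083 without control array 1 and 936 without control array 2 of the chamber set, to 933 and 884 without control arrays 1 and 2 of experiment 1, and to 723 without control array 1 of experiment 2. With only the chamber set in the model its count was 3714.

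Hypoxia in the chamber was set against hypoxia in the incubator to ask whether the devices gave different responses. Dstn, an actin-depolymerising factor, rose less in the chamber set (0.21) than in experiments 1 and 2 (2.10 and 1.35; difference -1.51 ± 0.15, adjusted p = 9.6e-06), and so did Adm (1.76 against 2.89 and 3.18; difference -1.27). Ftsj3 (-1.19, with a further probe set at 0.02), Tgif1 (-1.17), Vcl (-1.15) and the inducible heat shock gene Hspa1b (-1.14) also had lower values in the chamber. The plasminogen activator gene Plat (0.98 ± 0.16, adjusted p = 0.0039), Mxd4 (0.93), Ache (0.84), the transcription factor gene Jun (0.81), Tmem71 (0.79) and the cyclin gene Ccnd2 (0.79) had higher ones. Ribosome biogenesis fell further in the chamber: 32 of 42 genes fell there (median -0.72), 11 in experiment 1 (median -0.11, not called) and 21 in experiment 2 (median -0.43, adjusted p = 0.014 with an estimated correlation), and the difference was lower for 9 genes, 22 adjusted over the list alone (median -0.37, adjusted p = 2.1e-15, and 0.021 with an estimated correlation). In all, 178 genes differed, 31 higher and 147 lower. Camera called 6 further lists lower in the chamber, and none of them held: estimated-correlation adjusted p values were 0.16 for the unfolded protein response and heat shock, 0.37 for DNA replication, mitosis and oxidative phosphorylation, and 0.43 for the tricarboxylic acid cycle. Only Dstn and Adm of these 12 genes kept their call without any single array; each other gene lost it without control array 1 or 2 of the chamber set (adjusted p from 0.051 to 0.20). Ache and Ccnd2 lost it without 5 other arrays each and Hspa1b without 7 (adjusted p from 0.050 to 0.092). The count was 21 without chamber control 1, 9 without chamber control 2, 65, 54 and 86 without chamber hypoxia arrays 1, 2 and 3, 86 without experiment 1 control 1, 102 without experiment 1 hypoxia array 2, 92 and 111 without experiment 2 controls 1 and 2, and 109 and 102 without experiment 2 hypoxia arrays 1 and 2.

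Experiments 1 and 2 used the same device, and their hypoxia effects differed for 27 genes, 11 higher and 16 lower in experiment 1. The matricellular genes Ccn2 (1.67 ± 0.24, adjusted p = 0.0016) and Ccn1 (1.51) rose more in experiment 1, as did Srxn1 (1.34, with a further probe set at 0.07), Lcp1 (1.26, with a further probe set at 0.65), Id3 (1.10) and Gadd45a (0.97, adjusted p = 0.041). The thioredoxin-binding gene Txnip (-2.30, adjusted p = 7.1e-06, with a further probe set at 0.09), Bnip3 (-1.62), Synpo (-1.56), Rassf1 (-1.55), the mTOR inhibitor gene Ddit4 (-1.36) and Pcyox1 (-1.16) had lower values in experiment 1. Camera called 7 lists, 5 higher and 2 lower, and none held: the lowest adjusted p was 0.053 with an estimated correlation, for ribosome biogenesis (median 0.28). The count was 14 and 8 without control arrays 1 and 2 of experiment 1, 17 without control 1 of experiment 2 and 15 without its hypoxia array 2. Without control 1 of experiment 1 the calls of Ccn1 and Id3 (both adjusted p = 0.060), Srxn1 (0.082), Gadd45a (0.26) and Pcyox1 (0.060) were lost, and without control 2 those of Rassf1 (0.098), Ddit4 (0.075), Ccn1 (0.10) and Pcyox1 (0.13). Without control 1 of experiment 2 Ccn1 (0.083), Srxn1 (0.093) and Pcyox1 (0.13) lost theirs, Pcyox1 also without hypoxia arrays 2 or 3 of experiment 2 (both 0.054), and Gadd45a was called without 1 of the 10 arrays alone.

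The CoCl2 arrays of experiment 3 showed what the chemical mimic changed (4 CoCl2 and 2 control arrays). As the mean of both doses, the chemokine gene Ccl5 rose most, by 6.04 ± 0.13 (adjusted p = 9.1e-19; 5.72 at 100 µM and 6.37 at 200 µM). Lgals3 (4.71), Gm9706 (4.40), Ier3 (3.69), Bnip3 (3.47), Pkp2 (3.44), the interferon-induced genes Isg15 (3.43) and Isg20 (3.08), the macrophage-associated Cd68 (3.24, with a further probe set at 0.14) and the haem oxygenase Hmox1 (3.16) followed. The deepest falls were those of Mki67 (-4.30, with a further probe set at 0.27), Pclaf (-3.95, with a further probe set at -0.24), the topoisomerase Top2a (-3.95), Cdc6 (-3.74), Limch1 (-3.69), Rrm2 (-3.28), the condensin gene Smc2 (-3.19), Kif23 (-3.16), Ect2 (-3.16) and Eps8 (-3.15). At 100 µM 3165 genes changed (1456 higher, 1709 lower) and at 200 µM 3468 (1628 higher, 1840 lower), with 817 higher and 1350 lower at both doses. With only the arrays of experiment 3 these counts were 1197 and 1757. Its CoCl2 pairs vary more than the other groups, and that fit has fewer residual degrees of freedom. With the Actb 3′ minus 5′ value as a covariate, added after the data were seen, 1727 genes changed at 100 µM. That covariate is fitted on differences within groups, mostly between the 200 µM arrays, so it cannot settle the part of RNA quality at 100 µM. The 100 µM count was 1928 without control array 1 and 1952 without 100 µM array 1.

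Changes at the doses correlated at 0.854 across genes, which are not independent replicates. Both doses share their 2 control arrays, and unchanged groups simulated against shared controls gave 0.50 over 100 draws, with a covariance of 0.0113 against the observed 0.343. Independent lists of these sizes would share 287 higher and 381 lower genes, against 817 and 1350 found. Shared controls raise such overlaps by themselves, and the overlap they would give was not computed. With 1 control array for each dose, a comparison added after the data were seen, the correlation was 0.822 or 0.810 by assignment and the covariance 0.337 or 0.331, with no shared control.

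Cell division genes fell with CoCl2. Of 38 mitosis genes 36 fell and none rose (median -2.22, camera adjusted p = 1.5e-31), and of 40 DNA replication genes 35 fell and 3 rose (median -1.44, adjusted p = 5.1e-23), with the helicase subunits Mcm3 (-2.57) and Mcm2 (-2.52). Of 18 melanocyte and pigment genes 15 fell and 2 rose (median -1.28, adjusted p = 1.2e-09), including Tyr (-2.97 ± 0.25), Dct (-2.56), the melanosome matrix gene Pmel (-2.48), Tyrp1 (-2.41, with a further probe set at -0.19) and Mitf (-1.77). This list also holds the cell cycle kinase gene Cdk2 (-2.92, with a further probe set at -0.25), whose fall was larger than that of Dct. Ribosome biogenesis had 26 falls of 42, 28 adjusted over the list alone (median -0.58, adjusted p = 3.6e-09), such as Nop56 (-2.17) and Nhp2 (-1.81). For the mean of both doses these calls held with an estimated correlation (adjusted p = 0.0051 for the first 3 lists and 0.028). At 200 µM alone ribosome biogenesis, with 22 falls and 3 rises, did not hold (adjusted p = 0.18 with an estimated correlation, against 0.0058 at 100 µM). Tricarboxylic acid cycle genes fell in 15 of 25 cases and rose in 2, 16 and 2 adjusted over the list alone (median -0.48, adjusted p = 0.00015), with Idh2 (-1.83) and Suclg2 (-1.71). Oxidative phosphorylation had 21 falls and 6 rises of 45, 22 and 7 adjusted over the list alone (median -0.33, adjusted p = 0.0046), with Sdhb (-1.29) and Cycs (-1.20). Neither of these held (adjusted p = 0.24 and 0.34 with an estimated correlation). The Actb 3′ minus 5′ signal was 2.36 and 2.16 at 100 µM and 1.47 and 0.50 at 200 µM, against 1.41 and 1.62 in the controls.

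HIF targets and glycolysis genes rose in the same arrays. Of 21 HIF targets 18 rose and 1 fell (median 1.64, camera adjusted p = 8.1e-13), among them Vegfa (2.49), Ndrg1 (2.11) and Adm (1.15), and of 18 glycolysis genes 15 rose and none fell (median 0.89, adjusted p = 1.1e-08), among them Slc2a1 (2.80), Pfkp (2.08), Pgk1 (0.74) and Ldha (0.59). Both held with an estimated correlation for the mean of both doses (adjusted p = 0.0098 and 0.042), but glycolysis did not at 200 µM alone (adjusted p = 0.064, and 0.048 at 100 µM). Of 33 interferon and antigen presentation genes 14 rose and 4 fell, 16 and 5 adjusted over the list alone (median 0.26, adjusted p = 0.0020, and 0.019 with an estimated correlation, or 0.0056 at 100 µM and 0.084 at 200 µM), among them the RNA sensor Ifih1 (2.62), the antiviral gene Rsad2 (2.60), H2-K1 (2.52, with a further probe set at 0.36), the chemokine Cxcl10 (2.44) and H2-D1 (2.27). Oxidative and metal stress genes rose in 15 of 33 cases and fell in 4 (median 0.22, adjusted p = 0.0025), with the peroxiredoxin reductase Srxn1 (2.76), the autophagy adaptor Sqstm1 (2.57) and the glutathione synthesis gene Gclm (2.11), while the metallothionein Mt1 (0.40, adjusted p = 0.49) did not pass. Epithelial markers rose in 7 of 12 cases (median 0.31, all genes 0.12, adjusted p = 0.023), with Dsp (0.74, with a further probe set at 0.02) and Krt18 (0.40, with a further probe set at 0.08). These 2 calls were lost at adjusted p = 0.24 with an estimated correlation, and the epithelial one also without 200 µM array 1 (adjusted p = 0.054). For each list called with CoCl2, counts adjusted over the list alone were the same where not given. With only experiment 3 arrays Ldha (adjusted p = 0.056) and Krt18 (adjusted p = 0.070) did not pass, and Mt1 was -0.45 without 200 µM array 2 and 1.26 without 200 µM array 1 (adjusted p = 0.015 and 5.9e-07). In these groups the Actb 3′ minus 5′ signal reached 2.36 at 100 µM.

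Another 14 lists were not called for the mean of both CoCl2 doses. Hif1a (-0.27, adjusted p = 0.11) did not pass, and it did without 100 µM array 2 (-0.41, adjusted p = 0.0061) or without 200 µM array 1 (-0.37, adjusted p = 0.034). Epas1 (0.32, adjusted p = 0.034) passed, but not without control array 1 (adjusted p = 0.11), control array 2 (0.15), 100 µM array 1 (0.14) or 200 µM array 1 (0.074). It also did not pass with quantile normalisation (0.19, adjusted p = 0.17), array weights (0.091) or only experiment 3 arrays (0.19). Of 14 HIF pathway components 5 rose and 2 fell (adjusted p = 0.53), and of 12 glycogen genes 5 rose, such as Gys1 (1.93) and Gbe1 (1.90), and 3 fell, such as the phosphorylase Pygb (-1.20) (adjusted p = 0.53). Matrix and invasion genes rose in 10 and fell in 12 of 42 cases, 10 and 13 adjusted over the list alone (median 0.10, mean -0.02, camera direction down, adjusted p = 0.80), with the protease inhibitor Timp3 (-2.34) and the collagen Col4a1 (-1.77) among the falls. Angiogenic factors rose in 5 and fell in 6 of 20 cases (median 0.13, mean -0.09, camera direction down, adjusted p = 0.76). Heat shock genes rose in 8 and fell in 5 of 22 cases (adjusted p = 0.53), with Hspa1b at 2.05. Of 13 leukocyte markers 3 rose and none fell (median 0.25, all genes 0.12, adjusted p = 0.052): Cd68, Cd79a (0.52) and Cd3e (0.39). Cd79a and Cd3e lost their calls without control array 1 (adjusted p = 0.096 and 0.064), Cd3e also without control array 2 (0.051), and both with only experiment 3 arrays (0.11 and 0.13). Of 13 fibroblast markers 3 rose and 2 fell (adjusted p = 0.53), and of 10 endothelial markers 2 rose and 1 fell (adjusted p = 0.59). Counts adjusted over the list alone were the same except where given.

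The higher dose was compared with the lower one (2 arrays each). Hspa1b was 3.11 ± 0.24 higher at 200 µM (adjusted p = 2.3e-08), the metallothionein Mt1 2.78 ± 0.55 (adjusted p = 0.0013; -0.99 at 100 µM and 1.79 at 200 µM against control), Lilr4b 2.19, Ier3 1.99, Hsph1 1.94 and Pkdcc 1.83. The pigment genes Tyrp1 (-2.63 ± 0.15, adjusted p = 2.9e-10, with further probe sets at -0.92, -0.57 and 0.04) and Dct (-2.19) were lower. So were the adhesion gene Cadm1 (-2.36, with further probe sets at -1.25 and -0.48) and the interferon-induced Ifit1 (-2.09). The desaturase Scd1 (-1.85, with a further probe set at 0.59) and Dhrs7 (-1.77) were lower too. Of 22 heat shock genes 13 were higher and none lower, 14 adjusted over the list alone (median 0.62, adjusted p = 2.1e-12, and 0.0034 with an estimated correlation). Of 18 melanocyte genes 9 were lower, 10 adjusted over the list alone (median -0.55, adjusted p = 1.1e-06, and 0.031 with an estimated correlation). Of 42 ribosome biogenesis genes 18 were higher and 1 lower, 20 and 2 adjusted over the list alone (median 0.31, adjusted p = 4.6e-09, and 0.04996 with an estimated correlation). Oxidative phosphorylation (15 of 45 higher; 18 higher and 1 lower adjusted over the list alone) was called at adjusted p = 7.3e-05, but not with an estimated correlation (adjusted p = 0.24). Cholesterol genes (6 of 20 lower; adjusted p = 0.019), fatty acid genes (6 of 25 lower, 7 adjusted over the list alone; adjusted p = 0.019) and interferon genes (8 of 33 lower and 1 higher, 9 and 1 adjusted over the list alone; adjusted p = 0.023) were lost too, at adjusted p = 0.41, 0.24 and 0.089 with an estimated correlation. In all 1376 genes differed, 646 higher and 730 lower, while the Actb 3′ minus 5′ signal was 2.36 and 2.16 at 100 µM against 1.47 and 0.50 at 200 µM. With that signal as a covariate, added after the data were seen, 154 genes differed, of which 100 were among the 1376, and Mt1 (-0.87, adjusted p = 0.52) and Ier3 (0.89, adjusted p = 0.19) did not pass. This covariate is fitted on differences within groups, mostly that between the 200 µM arrays. The lower count therefore does not measure how many genes RNA quality explains. The count was 134 with only experiment 3 arrays, where Mt1 had adjusted p = 0.11, and 631 without 200 µM array 2.

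Finally, CoCl2 was compared with hypoxia to ask how far the mimic gave the changes of low oxygen. Across genes the changes correlated at 0.571, with no shared control, and genes are not independent replicates. Among called genes 482 were higher under both (241 for independent lists), 1098 were lower under both (370) and 183 went opposite ways. Ccl5 (6.08 ± 0.15, adjusted p = 2.1e-17), Gm9706 (4.48), Isg15 (3.75), Rsad2 (2.82), Ifih1 (2.74) and Cxcl10 (2.54) were higher with CoCl2 than in hypoxia. Mki67 (-4.11 ± 0.20, adjusted p = 2.5e-12, with a further probe set at 0.21), Ahr (-3.97), Top2a (-3.89), Ccn2 (-3.81), the protease Prss23 (-3.50) and Nppb (-3.49) were lower. Mitosis genes were lower in 32 of 38 cases, 33 adjusted over the list alone (median -2.01, adjusted p = 3.8e-39, and 0.0030 with an estimated correlation), and melanocyte genes in 14 of 18 with 1 higher (median -1.07, adjusted p = 4.8e-12, and 0.0030). DNA replication genes were lower in 29 of 40 cases, with 1 higher adjusted over the list alone (median -0.89, adjusted p = 1.6e-16, and 0.0072 with an estimated correlation). Interferon genes were higher in 13 and lower in 3 of 33 cases, 14 and 3 adjusted over the list alone (median 0.34, adjusted p = 0.00033, and 0.0072 with an estimated correlation). Matrix and invasion genes were lower in 15 and higher in 1 of 42 cases, 16 and 5 adjusted over the list alone (median -0.18, adjusted p = 0.0021, and 0.0072 with an estimated correlation). Camera called 8 further lists that did not hold with an estimated correlation: oxidative and metal stress (adjusted p = 0.19), the unfolded protein response (0.46) and epithelial markers (0.33) on the higher side, and angiogenic factors (0.077; median 0.01, mean -0.42), glycogen (0.12), oxidative phosphorylation (0.46), the tricarboxylic acid cycle (0.37) and ribosome biogenesis (0.34) on the lower side. In total 2092 genes differed, 770 higher and 1322 lower with CoCl2, where the Actb 3′ minus 5′ signal was 0.50 to 2.36 in the CoCl2 arrays and 0.15 to 0.50 in the hypoxia sets. The count was 1182 without control array 1 of experiment 3 and 3409 without 100 µM array 2.

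**Figure D4:**
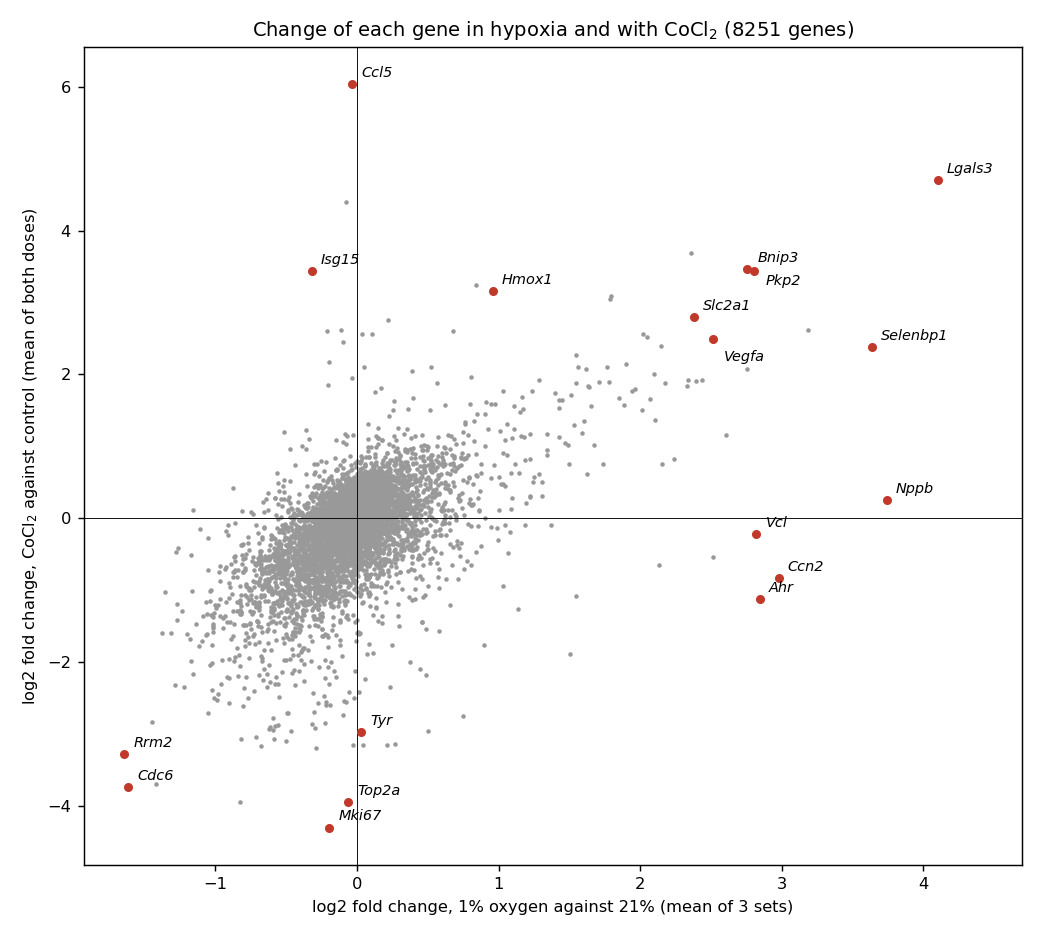
Log2 change of each of 8251 genes in hypoxia (mean of 3 sets, horizontal axis) and with CoCl2 (mean of both doses, vertical axis), with 18 named genes in red. Lgals3, Bnip3 and Vegfa lie high on both axes, Ccl5 (6.04) and Isg15 (3.43) on the CoCl2 axis, and Nppb (3.74) and Vcl (2.82) on the hypoxia axis.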

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

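The tests of leukocyte genes and of the Actb covariate on the interferon genes, and the test of 200 µM array 2 alone, were chosen only after the result was seen.

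The Actb 3′ minus 5′ signal, from control probe sets outside the gene tests, reached 2.36 in a CoCl2 array, above the controls of experiment 3 (1.41 and 1.62), and 1376 genes differed between the CoCl2 doses. Across these genes, 100 µM minus 200 µM correlated at 0.656 with the difference between the 2 arrays of the 200 µM group, whose Actb values were 1.47 and 0.50 (all genes 0.433). It correlated at 0.606 with the controls of experiment 3 minus the other controls, so differences in RNA quality are a candidate explanation for many of these genes. With array 1 minus array 2 at 100 µM (Actb 2.36 and 2.16) the correlation was -0.147. RNA quality as measured by Actb would give the opposite sign there. The Gapdh values (1.44 and 2.18) ranked these 2 arrays the other way. So did the transferrin receptor (2.18 and 2.41) and pyruvate carboxylase (1.12 and 1.21) controls. The sign therefore cannot decide about RNA quality. The 200 µM array 2 enters both sides of the 0.656, so a deviation of that array alone could also produce it. Without 200 µM array 2, 573 of the 1376 were still called, and with the Actb covariate 100 were. The slope of that covariate rests mostly on the 200 µM arrays themselves, so the 100 does not measure the share due to RNA quality. An effect of dose, which the design names, stays open beside RNA quality and that single array, since dose and RNA quality moved together.

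Interferon genes differed between treatments, with 13 of 33 called higher with CoCl2 than in hypoxia (median of the 13, 0.72). Leukocytes among the cells are not fully excluded: of 5 leukocyte genes picked from the 13 markers measured, 0 were called higher by limma (Ptprc -0.00, adjusted p = 0.99; Tyrobp 0.19, 0.33; Laptm5 -0.16, 0.36; Fcer1g 0.26, 0.30; Lyz2 0.13, 0.63), but 2 of all 13 were and none lower (Cd68 2.40 and Cd79a 0.47; camera adjusted p = 0.12). RNA quality is not settled by the Actb covariate, with which 13 of the 13 were still called higher (median 0.73). Each group has its own mean, so the covariate is fitted on differences within groups, mostly that between the 200 µM arrays (1.47 and 0.50). It cannot test the offset in RNA quality between experiment 3 and the hypoxia sets. A low baseline in the controls of experiment 3 is argued against because the CoCl2 arrays lay a median of 1.85 log2 units above the controls of the other sets, with 11 of 13 genes higher, while the controls of experiment 3 differed from those by -0.10. An interferon response to CoCl2 may account for these genes, as a hypothesis from the same 4 CoCl2 arrays. The labels name only cultured B16-F10 cells and thus no source of leukocytes. RNA quality and any other difference between experiment 3 and the hypoxia sets stay open.

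The hypoxia effect differed between chamber and incubator for 178 genes and 7 lists. A smaller response of the same kind in the chamber is argued against for these genes. Of them 18.0% (32) had the same sign and the smaller size there. In 53 the sign was the same and the size larger, and 93 had the opposite sign. The slope of the chamber effect on the incubator effect was 0.876 over the 1939 genes called in experiment 1 or 2. It adds nothing against a smaller response, because it is under 1 and these genes were picked by their incubator effect. Differences that arise between any sets of arrays are consistent with the test that took each set in turn as the odd one, which gave 184 genes for experiment 1 and 4 for experiment 2. The device stays open, because device and set cannot be separated with 1 chamber set. The count was 9 without control array 2, 21 without control array 1 of the chamber set, between 54 and 111 without a chamber hypoxia array (1, 2 or 3), experiment 1 control 1 or hypoxia 2, or experiment 2 control 1 or 2 or hypoxia 1 or 2, and within 1.5 times of 178 without any other.

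The difference between experiments 1 and 2 covered 27 genes, and 14 and 8 without control arrays 1 and 2 of experiment 1, 17 without control 1 and 15 without hypoxia array 2 of experiment 2. The difference between CoCl2 and hypoxia covered 2092 genes and 13 lists; the count was 1182 without control array 1 of experiment 3 and 3409 without 100 µM array 2. Regrouping single arrays between sets gave as many as the 178 genes in 1 of 100 cases, the real one (highest other 1). For the 27 genes this was 1 of 60 (highest other 3) and for the 2092 genes 1 of 100 (highest other 2). Variation shared by the arrays of a treatment within a set enters the residual spread of other regroupings and lowers their counts. They therefore show only that single arrays were not interchangeable between sets. Whether whole sets differed by chance these regroupings cannot decide. For the 2642 genes of hypoxia, 1 of 100 splits within the sets gave as many, the real one (highest other 1026). Were the arrays interchangeable within the sets, the real split would rank first in 1 of 100 cases. Other splits mix hypoxia and control arrays, which lowers their counts, so the size of the gap adds nothing to that rank. For the number of lists called in hypoxia (8) the splits cannot decide: 30 of 100 gave as many and the highest other 13, but every other split keeps part of the difference between hypoxia and control arrays. In a comparison added after that result was seen, the medians of 7 of these 8 lists were exceeded in no other split. These were 1.64 for HIF targets against a highest other of 1.21 and -0.70 for DNA replication against 0.48 in size. The tricarboxylic acid cycle median was equalled or exceeded in 2 others. Other splits dilute a shift that hypoxia makes, so the size of these gaps adds no evidence of its own.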

How the results depend on the processing

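The Actb covariate, the crossed replicate numbers, the split of controls between CoCl2 doses and the run without probe sets ending in _f_at were chosen only after the result was seen. Array signal near background limits what can be seen of dim genes, and the deposited values carry no detection calls used here. For the genes named, 3735 of the results under an alternative kept the call or the lack of one. Genes called in neither fit could change sign among these. A further 97 kept direction and lost the call, and 8 kept direction and gained it. In 2 results, both of Mt1, the sign turned with a call before or after. For the called lists and the rest, 372 results kept their call and 12 lost it, 6 of them with an estimated correlation, and the others were epithelial markers with CoCl2 (adjusted p = 0.11 with quantile normalisation, 0.33 without dim genes, 0.091 with a variance trend, 0.054 without 200 µM array 1) and oxidative phosphorylation with CoCl2 (0.082 without dim genes, 0.064 with a variance trend). Without probe sets ending in _f_at 2594 genes changed in hypoxia and 143 differed for chamber minus incubator. The hypoxia count kept within 1.5 times of 2642 under each alternative run except the 1 log2 threshold. Unless stated, the cause was not tested. The thresholds lower counts by construction, and leaving arrays out also removes samples.

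With array weights the chamber count was 4150, chamber minus incubator 1876, experiment 1 minus experiment 2 123, CoCl2 100 µM 1616 and the dose difference 242. With only arrays of the compared sets the chamber count was 3714, chamber minus incubator 1034, experiment 1 minus experiment 2 57, CoCl2 100 µM 1197, CoCl2 200 µM 1757 and the dose difference 134. Quantile normalisation gave 117 for chamber minus incubator. Leaving out dim genes gave a correlation of 0.808 between the chamber set and experiment 2. At an adjusted p under 0.01 the counts were 1172 (chamber), 959 (experiment 1), 825 (experiment 2), 34 (chamber minus incubator), 9 (experiment 1 minus experiment 2), 1973 (CoCl2 100 µM), 758 (dose) and 1273 (CoCl2 minus hypoxia). With at least 1 log2 unit they were 160 (hypoxia), 219 (chamber), 180 (experiment 1), 167 (experiment 2), 13 (chamber minus incubator), 12 (experiment 1 minus experiment 2), 598 (CoCl2 100 µM), 876 (CoCl2 200 µM), 157 (dose) and 377 (CoCl2 minus hypoxia). Called lists were 21 with fry for hypoxia, and 7 with an estimated correlation and 20 with fry for CoCl2. With the Actb covariate CoCl2 100 µM gave 1727 and the dose difference 154, and Mt1 turned from 2.78 to -0.87 for the dose difference. The slope of this covariate comes mostly from the 200 µM pair, so these values are no correction for RNA quality between groups. Gadd45a, named for experiment 1 minus experiment 2, lost its call with this covariate (adjusted p = 0.058) and with median centring (0.060). Mt1 gained a call in hypoxia with array weights (adjusted p = 0.00083) and the covariate (0.0095), and with CoCl2 with the covariate (0.026).

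Pairing by replicate number is neither stated by the labels nor excluded by the residuals. With that number as a block, the counts were 1136 (chamber), 827 (experiment 1), 813 (experiment 2), 5 (chamber minus incubator), 3 (experiment 1 minus experiment 2), 892 (dose) and 1391 (CoCl2 minus hypoxia). Under this block 10 of the 12 genes named for chamber minus incubator, 9 of the 12 for experiment 1 minus experiment 2, and Epas1 with CoCl2 (adjusted p = 0.052) lost their calls. With the numbers of the 100 µM group crossed, the block gave 2622 at 100 µM, 3040 at 200 µM and 1046 for the dose difference.

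Leaving out single arrays gave 2238 to 2635 genes for hypoxia, 936 to 1633 for the chamber, 884 to 1330 for experiment 1, 723 to 1091 for experiment 2, 9 to 189 for chamber minus incubator, 8 to 29 for experiment 1 minus experiment 2, 1928 to 4196 for CoCl2 100 µM, 2404 to 3190 for CoCl2 200 µM, 631 to 1975 for the dose difference and 1182 to 3409 for CoCl2 minus hypoxia. Lists ranged from 8 to 9 for hypoxia and from 10 to 12 for CoCl2. The mean CoCl2 change of Mt1 lay between -0.45 and 1.26.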

Other observations

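The proteasome and actin lists, and their tests, were chosen only after the result was seen.

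Further gene groups moved in mixed directions in hypoxia. Fatty acid genes rose in 6 and fell in 7 of 25 cases, 6 and 8 adjusted over the list alone (adjusted p = 0.48): the elongase Elovl6 (-1.20 ± 0.07), the mitochondrial carnitine palmitoyltransferase Cpt1a (-1.18 ± 0.06) and the fatty acid synthase Fasn (-1.05) fell, and the malic enzyme Me1 rose by 0.87. Of 22 p53 targets 7 rose and 4 fell, 7 and 5 adjusted over the list alone (median -0.01, mean 0.16, camera direction up, adjusted p = 0.33), with the cell cycle inhibitor Cdkn1a at 1.85 and the kinase Plk2 at 1.59. Unfolded protein and integrated stress response genes fell in 14 and rose in 4 of 37 cases, 15 and 7 adjusted over the list alone (median -0.18, adjusted p = 0.053): Slc7a5 (-0.97) and Psat1 (-0.75) fell, and the stress transcription factor Atf3 rose by 1.79 (a further probe set at -0.05). Of 33 oxidative and metal stress genes 8 rose and 6 fell, 10 and 6 adjusted over the list alone (adjusted p = 0.22), with Hmox1 at 0.96, while the metallothioneins Mt1 (0.64, adjusted p = 0.10) and Mt2 (0.47) did not pass; with only the arrays of the hypoxia sets Mt1 did (adjusted p = 1.0e-08). Iron handling genes rose in 4 and fell in 1 of 13 cases (adjusted p = 0.25), with ceruloplasmin (Cp) at 1.03 and the transferrin receptor Tfrc at -0.03. Cholesterol genes rose in 3 and fell in 3 of 20 cases (median -0.03, mean -0.00, camera direction up, adjusted p = 0.91). Of 13 housekeeping genes 4 rose and 1 fell (median 0.10, mean -0.02, camera direction up, adjusted p = 0.64), and the fall was that of Gusb (-1.22). Here and for CoCl2, counts adjusted over the list alone were the same where not given.

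With CoCl2, Cpt1a (-1.68) and Elovl6 (-1.62) fell as well, among 9 falls and 5 rises of 25 fatty acid genes, 9 and 6 adjusted over the list alone (median 0.03, mean -0.16, camera direction down, adjusted p = 0.46). Cdkn1a rose by 1.68, among 6 rises and 5 falls of 22 p53 targets, 7 and 5 adjusted over the list alone (adjusted p = 0.44). Atf3 (3.05, with a further probe set at 0.19), the stress factor gene Ddit3 (1.58) and Slc7a11 (1.63) rose and Psat1 (-1.54) fell, among 10 rises and 9 falls of 37 unfolded protein and stress response genes, 12 and 9 adjusted over the list alone (adjusted p = 0.90). Cp fell by 0.95 and Tfrc rose by 0.46 (not passing without control array 1, with only experiment 3 arrays or with array weights, adjusted p = 0.11, 0.056 and 0.052), among 3 rises and 3 falls of 13 iron genes (adjusted p = 0.53). Cholesterol genes rose in 5 and fell in 3 of 20 cases (median 0.04, mean -0.02, camera direction up, adjusted p = 0.90), and housekeeping genes rose in 3 and fell in 3 of 13 (median 0.07, mean -0.12, camera direction down, adjusted p = 0.75), with Gusb at -2.35. The Actb 3′ minus 5′ signal was 0.50 to 2.36 in these arrays.

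A hypothesis was that proteasome genes rise together with CoCl2. Of 31 subunit genes 19 rose and none fell for the mean of both doses by limma (median 0.47, all genes 0.12; camera p = 1.2e-05), but the p was 0.074 with an estimated correlation, so this stays open. At 200 µM the median was 0.61 (p = 0.028 with an estimated correlation) and at 100 µM 0.17 (p = 0.31), but with the Actb covariate the medians were 0.51 and 0.43. That covariate is fitted mostly on the difference between the 200 µM arrays. In hypoxia 15 of the genes fell and 1 rose (median -0.22; p = 0.16 with an estimated correlation), and the difference between CoCl2 and hypoxia was higher for 23 genes (median 0.62; p = 0.010).

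A further hypothesis was that genes of the actin cytoskeleton and targets of serum response factor rise in hypoxia and not with CoCl2. Of 37 genes 14 rose and 2 fell in hypoxia (median 0.14; p = 0.00021 with an estimated correlation), and 8 rose and 9 fell with CoCl2 (median 0.18, all genes 0.12; p = 0.96). The difference between CoCl2 and hypoxia was lower for 12 genes and higher for 1, with a median of -0.036 against 0.09 for all genes (p = 0.0034 with an estimated correlation). The test is in line with the hypothesis, although the median with CoCl2 was no lower than in hypoxia, and the list, which holds neither gene, was drawn up after the changes of Vcl and Ccn2 had been seen.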
